A study of Homo sapiens with 14 samples.

How the data were processed

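HEK293T cells treated with RNA base editors were sampled by RNA sequencing. Total RNA was taken up in TRIzol, polyadenylated RNA was enriched on magnetic beads and directional libraries were built, per the labels' protocols. The 14 libraries were placed in 7 groups of 2 from their titles. These were REPAIRv2 with the NT or EZH2_A22 guide, REPAIR.t1 with the NT or EZH2_A22 guide, dCas13d-ADAR with the NT or EZH2 guide, and DECOR with the MALAT1 guide.

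The authors deposited 1 list per library, with the chromosome, the position and the A-to-G rate of each site as a fraction from 0 to 1, per the file headers. The rate was read as the editing level. The submitters' processing notes name cutadapt, a read trimmer, STAR 2.6.1b, a read aligner, and the builds hg19 and GRCh37, without a role or order. The site caller, its thresholds, any coverage minimum and the treatment of genomic variants are not given in the sources used here. No list held a level below 0.05. The lists hold no read counts, no coverage and no strand, so the depth of each library and site is unknown and no counting error could be attached to a level. Which sites a library lists depends on its depth, so numbers of sites and overlaps between lists mix editing with detection.

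The number of sites, the median level, the share of sites at a level of at least 0.5 and the overlap of positions were computed per library. Editors were compared by two-sided exact permutation tests of log10 site numbers and of median levels, 4 libraries against 4 (70 arrangements) or 4 against 2 (15 arrangements), with Benjamini-Hochberg adjustment over the 3 pairs of REPAIRv2, REPAIR.t1 and dCas13d-ADAR and over the 3 pairs with DECOR. All exact tests between editors pooled the NT and EZH2 libraries of an editor and permuted labels without regard to guide. EZH2 and NT guides were compared with labels permuted within each of 3 editors. Overlap was the share of the shorter list found at the same position in the other, and the Jaccard index.

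Levels per site were compared on log2 odds, with 0.01 added to the level and to its complement, in limma 3.58.1 with empirical Bayes moderation and an adjusted p threshold of 0.05. A test on read counts had been set as the first choice before the data were examined, and this limma test was the fallback fixed beside it for lists without counts. Tests used sites listed in all libraries compared, with the guide as a covariate between REPAIR.t1 and dCas13d-ADAR. The test was tried on simulated data with 100 sites changed by 1 and 100 by 2 log2 units of odds (4 and 4 for the comparison of DECOR). The share recovered for 1 and 2 units was 49% and 100% for the comparison of dCas13d-ADAR with REPAIR.t1, and 25% and 100% for that with DECOR.

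Sites are named by a rule fixed before the data were examined. It takes, per comparison, the 10 largest rises and 10 largest falls in mean level among sites with an adjusted p below 0.05 and no overlap between the libraries of the 2 sides, per editor the 10 highest mean levels among sites in all its libraries, of which the first few are printed, and the REPAIRv2 sites in at least 2 of its libraries, of which the 5 in all 4 libraries and those in no list of REPAIR.t1 or dCas13d-ADAR are printed. Other named sites are said to have been chosen after their values were seen.

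Alternatives were minimum levels of 0.1 and 0.2, sites in both libraries of a group, positions within 50 bases counted as shared (without regard to strand, which the lists do not hold), each library left out in turn, the replicate number as a block, 1 guide at a time and no guide covariate. Chosen after seeing the data were untransformed levels, a trend of the spread on the mean, an added 0.001, sites missing from at most 1 library, the guide test without REPAIRv2, the alternatives for the share of sites on 4 chromosomes and for spacing, and those for sites listed by 1 editor only, for the mean level at shared sites and for the median level at shared REPAIRv2 sites. Gene names, the fixed gene lists, transcript regions, sites in the guides' target genes and sequence context were not analysed here, since the annotation at hand is of another build and holds no sequence.

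Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3; figures were drawn with matplotlib 3.10.9.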

Results

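The data were lists of adenosine sites that read as guanosine in RNA from HEK293T cells, a human embryonic kidney line that is easily transfected. Each list came from 1 library of polyadenylated RNA and gave, for each site, its chromosome, its position and the A-to-G rate, the fraction taken here as the editing level. The cells carried 1 of 4 RNA base editors, which are proteins meant to convert adenosine to inosine, a base that sequencing reads as guanosine. REPAIRv2 joins a catalytically inactive Cas13 protein to the deaminase domain of a human ADAR enzyme. The labels name the others REPAIR.t1, dCas13d-ADAR and DECOR. Guides are labelled NT, EZH2 (EZH2_A22 for REPAIRv2 and REPAIR.t1) and MALAT1, and the labels do not spell out NT or A22. The 14 libraries formed 7 groups of 2. DECOR was sampled with the MALAT1 guide alone, and its libraries were read for 62 and 160 cycles where all others were read for 25 and 97, so editor, guide and read length cannot be told apart for DECOR. The series asks how RNA editing compares between these editors.

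Positions are those of hg19 (GRCh37), the build in the submitters' processing notes. No annotation or sequence of that build was used, so genes, exons, strands and neighbouring bases of the sites were not analysed here. The read depth of the libraries and of each site is unknown, so no counting interval is given, and a site missing from a list may be unedited, edited below the authors' threshold or too thinly covered. Every library carried an editor, so no list shows which sites would be there without one. A listed site may therefore not be the work of the editor. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

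REPAIRv2 libraries listed far fewer sites than libraries of any other editor. REPAIRv2 gave 70.0 ± 28.3 sites (mean ± SD, n = 4 libraries), against 4647 ± 199 for REPAIR.t1 (n = 4), 5788 ± 43.0 for dCas13d-ADAR (n = 4) and 5686 ± 240 for DECOR (n = 2). The ratio of geometric means was 70.7 for REPAIR.t1 over REPAIRv2 and 88.1 for dCas13d-ADAR over REPAIRv2; with sites in both libraries of a group these ratios were 115.6 and 162.6. dCas13d-ADAR listed 1.25 times as many sites as REPAIR.t1, and the 4 dCas13d-ADAR libraries (5730 to 5834 sites) all lay above the 4 REPAIR.t1 libraries (4356 to 4784). Each of these 3 differences had p = 0.0286 in a two-sided exact permutation test of log10 site numbers, 4 libraries against 4, and 0.0286 after Benjamini-Hochberg adjustment over the 3; this is the smallest p that 70 arrangements allow. These tests pooled the NT and EZH2 libraries of an editor and permuted labels without regard to guide, and no permutation within guides was run. With 3 libraries against 4 the smallest possible p is 0.0571, so no difference could pass 0.05 when a library was left out.

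Without a minimum level, DECOR listed about as many sites as dCas13d-ADAR, at a ratio of 0.982 (two-sided exact permutation p = 0.667, adjusted 0.667). It listed 1.22 times as many as REPAIR.t1 and 86.5 times as many as REPAIRv2 (exact permutation p = 0.133 each, adjusted 0.2). With 2 libraries against 4, no p below 0.133 is possible. Among sites with a level of at least 0.2 the DECOR lists were shorter than the dCas13d-ADAR lists, at a ratio of 0.730 (exact permutation p = 0.133, adjusted 0.2), and than the REPAIR.t1 lists, at a ratio of 0.932, where the direction turned.

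**Figure D1:**
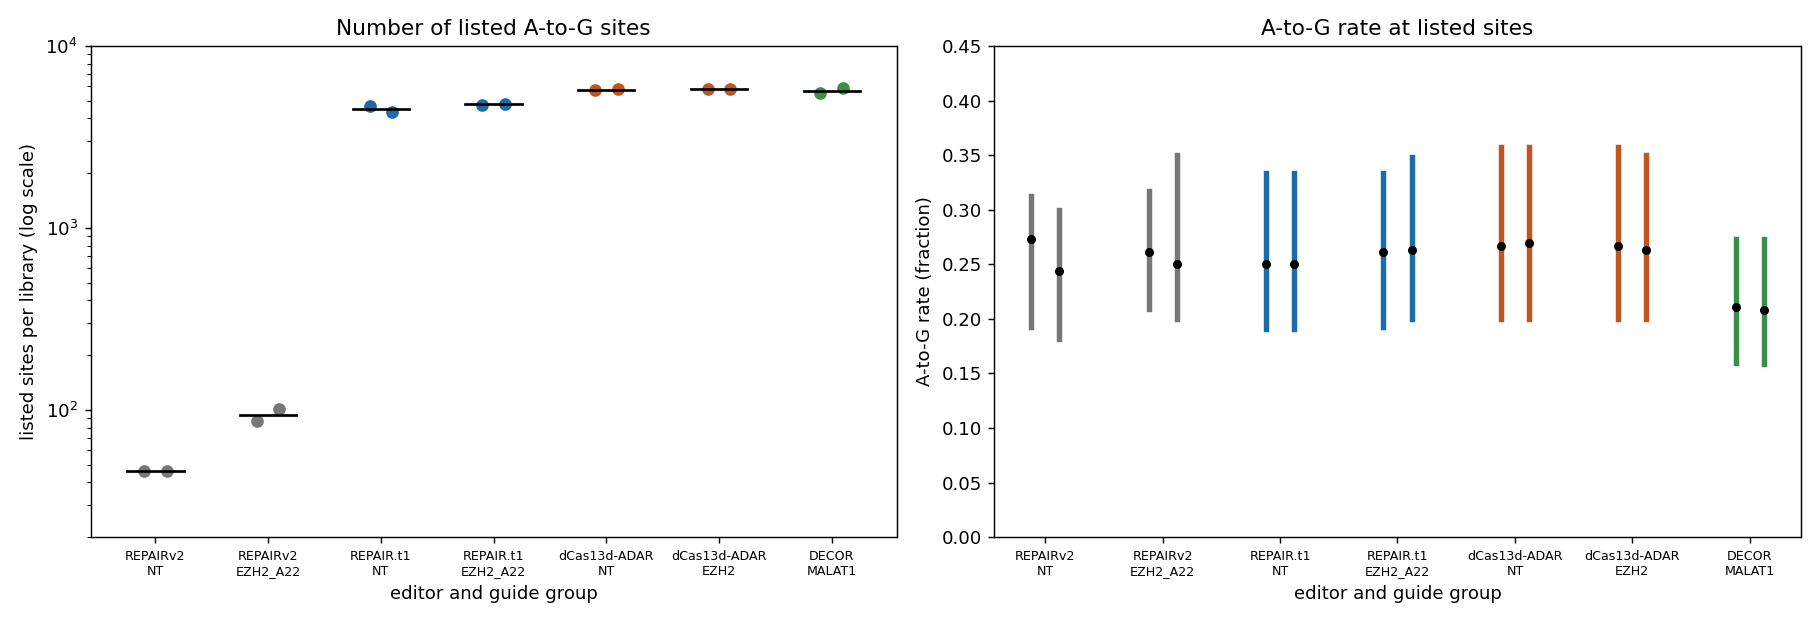
Left, the number of listed sites per library (log scale) for the 7 editor and guide groups, with points for libraries and lines for group means; the REPAIRv2 libraries hold 46 to 101 sites and the others 4356 to 5855. Right, the A-to-G rate (fraction) at the listed sites of each library, with the median as a black point and the interquartile range as a bar; the DECOR medians, 0.211 and 0.208, lie below the others.

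Median editing levels, each over a library's own list, were close together for the 3 editors run with NT and EZH2 guides and lower for DECOR. The median level per library averaged 0.266 ± 0.00249 for dCas13d-ADAR (SD, n = 4), 0.256 ± 0.00700 for REPAIR.t1 (n = 4), 0.257 ± 0.0126 for REPAIRv2 (n = 4) and 0.209 ± 0.00155 for DECOR (n = 2). Highly edited sites, at a level of at least 0.5, made up 6.88% ± 0.631 of the dCas13d-ADAR lists, 4.61% ± 0.378 of the REPAIR.t1 lists, 4.27% ± 1.88 of the REPAIRv2 lists and 1.69% ± 0.0215 of the DECOR lists. The difference in median level of dCas13d-ADAR minus REPAIR.t1 was 0.0104 (0.0162 with sites in both libraries of a group), which did not pass the two-sided exact permutation test (p = 0.0571, adjusted 0.171 over 3 pairs). The medians of REPAIRv2 did not differ detectably from those of REPAIR.t1 (REPAIR.t1 minus REPAIRv2, -0.000904, exact permutation p = 1) or dCas13d-ADAR (dCas13d-ADAR minus REPAIRv2, 0.00952, exact permutation p = 0.257), but these lists hold different sites. With sites in both libraries of a group the first difference turned to 0.00981 and the second was 0.0260. At the 34 to 84 sites in both lists of a pair of libraries, REPAIRv2 was lower in each pair, by 0.141 to 0.214 on average than REPAIR.t1 (16 pairs) and by 0.178 to 0.265 than dCas13d-ADAR (16 pairs), which was not tested. DECOR minus dCas13d-ADAR was -0.0570, with exact permutation p = 0.133, the smallest that 2 libraries against 4 allow.

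Taken over REPAIRv2, REPAIR.t1 and dCas13d-ADAR, libraries with an EZH2 guide listed more sites than NT libraries. The NT libraries of REPAIRv2 listed 46 and 46 sites and its EZH2_A22 libraries 87 and 101. The ratio of geometric means of EZH2 over NT libraries was 2.04 for REPAIRv2, 1.06 for REPAIR.t1 and 1.01 for dCas13d-ADAR. Over the 3 editors the mean ratio was 1.30 (two-sided exact permutation p = 0.0185, labels permuted within each editor). Within 1 editor, 2 libraries against 2 cannot give p below 0.333. Without the REPAIRv2 libraries the ratio was 1.03 and the exact permutation p was 0.111, where 36 arrangements allow no p below 0.0556. The ratio of REPAIRv2 was 1.97 times the mean ratio of the other 2 editors. This difference was not detected (two-sided exact permutation p = 0.324, labels permuted within each editor). With 2 REPAIRv2 libraries per guide, whether the ratio differs stays open. Median editing levels of EZH2 minus NT libraries differed by 0.00201 over the 3 editors (exact permutation p = 0.722). The directions differed, at 0.0120 for REPAIR.t1, -0.00295 for REPAIRv2 and -0.00304 for dCas13d-ADAR.

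Site by site, no change of editing level with the EZH2 guide was detected in REPAIR.t1 or dCas13d-ADAR cells. Of 1053 sites listed in all 4 REPAIR.t1 libraries, 0 passed an adjusted p of 0.05 in limma's moderated test on log2 odds, with 61 at an unadjusted p below 0.05 and a smallest adjusted p of 0.539. Of 1665 sites listed in all 4 dCas13d-ADAR libraries, 0 passed in limma, with 87 below an unadjusted 0.05 and a smallest adjusted p of 0.381. On simulated data of the same size the test recovered 87% of changes of 2 log2 units of odds for REPAIR.t1 and 73% for dCas13d-ADAR, but 18% and 11% of changes of 1 unit. The simulated data changed 100 sites by 1 and 100 by 2 units together. If a guide changes fewer sites, the share recovered is expected to be lower. The difference of the guide effect between the 2 editors was likewise passed by 0 of 609 sites in limma, with 41 at an unadjusted p below 0.05; without dCas13d-ADAR NT replicate 1, 1 site passed. REPAIRv2 had 5 sites in all 4 libraries, below the minimum of 20 set beforehand, and was not tested.

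Positions listed with 1 kind of guide alone were about as many for EZH2 as for NT guides. Over REPAIRv2, REPAIR.t1 and dCas13d-ADAR, 745 sites were in at least 2 EZH2 libraries and no NT library, against 696 the other way round, and 101 sites were in at least 3 EZH2 libraries and no NT library, against 87 sites in at least 3 NT libraries and no EZH2 library. In at least 4 libraries these numbers were 1 and 6. The EZH2 site was position 44204141 on chromosome 2, at a mean level of 0.329 in both EZH2_A22 libraries of REPAIR.t1 and both EZH2 libraries of dCas13d-ADAR. Among the 6 NT sites the highest mean level, 0.485, was at position 80856671 on chromosome 9. At 2 positions, 122753951 and 151789848 on chromosome 6, an EZH2 library of each of the 3 editors listed the site and no NT library did, against 0 positions the other way round. Each of the 2 was in only 1 EZH2 library per editor. The REPAIRv2 EZH2_A22 lists (87 and 101 sites) were longer than its NT lists (46 and 46), so more sites could qualify on the EZH2 side. All positions named here were singled out after their values were seen, and sites in the guides' target genes were not analysed.

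The lists of REPAIR.t1 and dCas13d-ADAR shared many positions with each other, while DECOR lists shared few with either. On average 45.3% of the shorter list was shared by 2 libraries of a REPAIR.t1 group, and 45.6% by EZH2_A22 and NT libraries of that editor. For dCas13d-ADAR these shares were 50.4% and 50.3%, and a REPAIR.t1 and a dCas13d-ADAR library shared 43.9% (42.9% to 44.6% over 16 pairs). The 2 DECOR libraries shared 37.5% with each other, but 1.57% with REPAIR.t1 libraries (1.35% to 1.88% over 8 pairs) and 1.98% with dCas13d-ADAR libraries (1.67% to 2.18% over 8 pairs). With the short REPAIRv2 lists the share of the shorter list was 7.54% without a minimum level (5.75% to 10.9% over 8 pairs). Within an editor, the Jaccard index of REPAIR.t1 and dCas13d-ADAR libraries was 6.68 percentage points higher than between these editors. This was more than in any other of the 35 splits of the 8 libraries (one-sided exact permutation p = 0.0286), and the highest other split gave 1.20 points. The Jaccard index also falls when 2 lists differ in length, and the dCas13d-ADAR lists were longer. The split test therefore cannot tell other positions from list length. Of the shorter list, 43.9% was shared between these editors, against 45.3% and 50.4% within groups of REPAIR.t1 and dCas13d-ADAR.

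**Figure D2:**
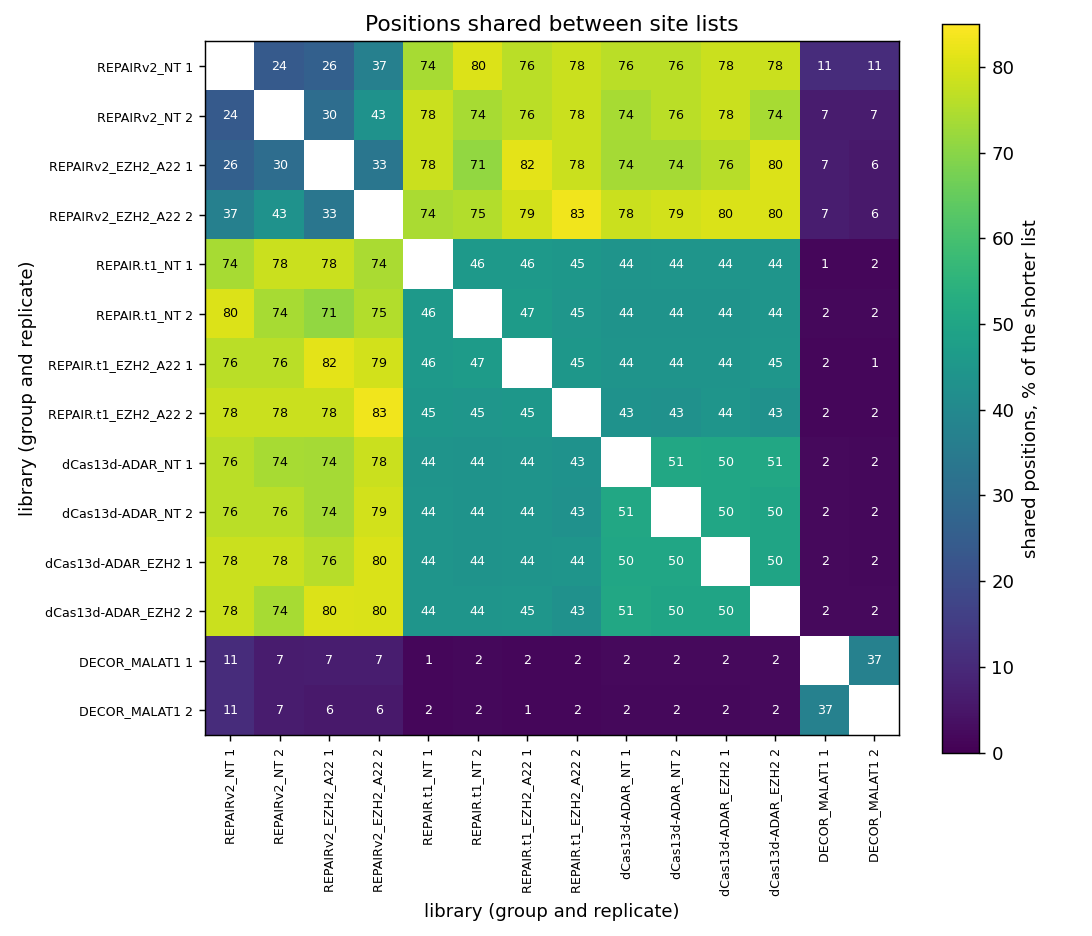
Positions shared by each pair of the 14 libraries, as a percentage of the shorter of the 2 lists (colour and printed value; axes name group and replicate). DECOR lists share on average 1.57% with REPAIR.t1 lists and 1.98% with dCas13d-ADAR lists, and 37.5% with each other.

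Pooled over libraries, the 4 editors listed 26172 distinct sites. REPAIR.t1 listed 10648 and dCas13d-ADAR 12349, of which 5803 were common to both. DECOR listed 9304, of which 349 (3.75%) were in any list of the other editors. Of the 2067 sites in both DECOR libraries, 95 (4.60%) were. Counting sites within 50 bases of each other as shared, DECOR and dCas13d-ADAR libraries shared 16.03% of the shorter list, DECOR and REPAIR.t1 libraries 14.3%, and the 2 DECOR libraries 48.1%.

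Most REPAIRv2 sites were also listed for the editors with longer lists. Of 205 distinct REPAIRv2 sites, 182 (88.8%) were in a REPAIR.t1 or dCas13d-ADAR list and 19 (9.27%) in a DECOR list. Of the 52 sites in at least 2 REPAIRv2 libraries, 50 were in a REPAIR.t1 or dCas13d-ADAR list; of the other 2, position 42855057 on chromosome 6 was also in both DECOR libraries, and position 180670790 on chromosome 5, at a mean level of 0.189 in both EZH2_A22 libraries, was in no list of another editor. Sites shared with REPAIRv2 had high levels in the other editors. Their median level was 0.386 ± 0.00430 in REPAIR.t1 libraries, against 0.255 ± 0.00542 for the remaining sites (SD, n = 4), and 0.436 ± 0.00601 in dCas13d-ADAR libraries, against 0.265 ± 0.00203 (SD, n = 4). In single REPAIR.t1 libraries the median of these shared sites exceeded 83.3% to 87.5% of the remaining sites. In single dCas13d-ADAR libraries it exceeded 89.0% to 90.8% of them.

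The 5 sites in all 4 REPAIRv2 libraries were edited at 0.301 to 0.359 on average. They were position 79614895 on chromosome 15 (0.359 ± 0.0671, SD, n = 4), position 156209533 on chromosome 1 (0.351 ± 0.0852), position 65048599 on chromosome 11 (0.337 ± 0.127), position 48362360 on chromosome 12 (0.314 ± 0.0814) and position 235277158 on chromosome 1 (0.301 ± 0.0368). All 5 were in every REPAIR.t1 and dCas13d-ADAR library. In dCas13d-ADAR libraries the site on chromosome 15 reached 0.751 ± 0.0567 and position 156209533 reached 0.736 ± 0.0802 (SD, n = 4). Position 235277158 was also in both DECOR libraries.

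Most of the highest sites of DECOR, like most of its sites at any level, were in no list of another editor. Among all DECOR sites 3.75% were in such a list, and among those in both its libraries 4.60%. Position 195778213 on chromosome 3 had the highest mean level of both REPAIR.t1 (0.877 ± 0.0534, SD, n = 4) and dCas13d-ADAR (0.751 ± 0.177). In REPAIR.t1 it was followed by position 150345451 on chromosome 3 (0.694 ± 0.0847) and position 139818310 on chromosome 9 (0.673 ± 0.175). In dCas13d-ADAR the next were the site on chromosome 15 above and position 48713401 on chromosome 8 (0.748 ± 0.0422). The 4 highest sites of DECOR were position 10194316 on chromosome 3 (0.779 ± 0.0143, SD, n = 2), position 30536603 on chromosome 8 (0.721 ± 0.00918), position 104164830 on chromosome 14 (0.655 ± 0.0168) and position 77083915 on chromosome X (0.639 ± 0.0393). None of these 4 was in a list of another editor, and of its 10 highest sites 1 was: position 77083891 on chromosome X (0.581 ± 0.0432), listed at 0.550 to 0.818 by REPAIRv2, REPAIR.t1 and dCas13d-ADAR libraries.

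At sites listed in every library of both editors, dCas13d-ADAR gave higher levels than REPAIR.t1. Over the 609 sites listed in all 8 libraries of the 2 editors, the mean level was 0.370 ± 0.00537 in dCas13d-ADAR (SD, n = 4; 0.365 to 0.377) and 0.320 ± 0.00971 in REPAIR.t1 (n = 4; 0.310 to 0.333). The difference of 0.0496 had p = 0.0286 in a two-sided exact permutation test, the smallest possible, and 455 of the 609 sites were higher in dCas13d-ADAR. These are 609 of the 5803 sites common to both editors; over the 1906 to 2124 sites in both lists of a pair of libraries the mean difference was smaller, at 0.0221 to 0.0381 (16 pairs). Site by site, 44 of the 609 differed at an adjusted p below 0.05 in limma, 40 of them higher and 4 lower in dCas13d-ADAR.

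The largest rises among sites whose libraries did not overlap were at position 62384095 on chromosome 11 (0.620 ± 0.0844 in dCas13d-ADAR against 0.340 ± 0.0595 in REPAIR.t1, SD, n = 4 each; limma log2 odds difference 1.65, SE 0.36, adjusted p = 0.00445) and position 42320953 on chromosome 20 (0.680 ± 0.0860 against 0.400 ± 0.0327; limma adjusted p = 0.00445). Position 35796553 on chromosome 22 rose from 0.362 to 0.629, position 24095325 on chromosome X from 0.433 to 0.685 and position 46190409 on chromosome 21 from 0.392 to 0.642. On chromosome 19, position 19014207 rose from 0.202 to 0.450 and position 36237649 from 0.178 to 0.408. Position 47106473 on chromosome X, position 99693705 on chromosome 7 and position 57100941 on chromosome 11 rose by 0.231, 0.222 and 0.220. The 3 sites that fell without overlap were position 30671149 on chromosome 7, from 0.573 ± 0.0661 to 0.321 ± 0.0599 (limma adjusted p = 0.00643), position 34101308 on chromosome 11, from 0.481 to 0.260, and position 125453683 on chromosome 11, from 0.440 to 0.233. The number of sites passing fell to 10 without dCas13d-ADAR NT replicate 1, to 27 without REPAIR.t1 NT replicate 2 and to 29 without REPAIR.t1 EZH2_A22 replicate 2. With NT libraries alone 2 of 1046 sites passed in limma (168 at an unadjusted p below 0.05), and with EZH2 libraries alone 0 of 1101 (114 at an unadjusted p below 0.05).

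**Figure D3:**
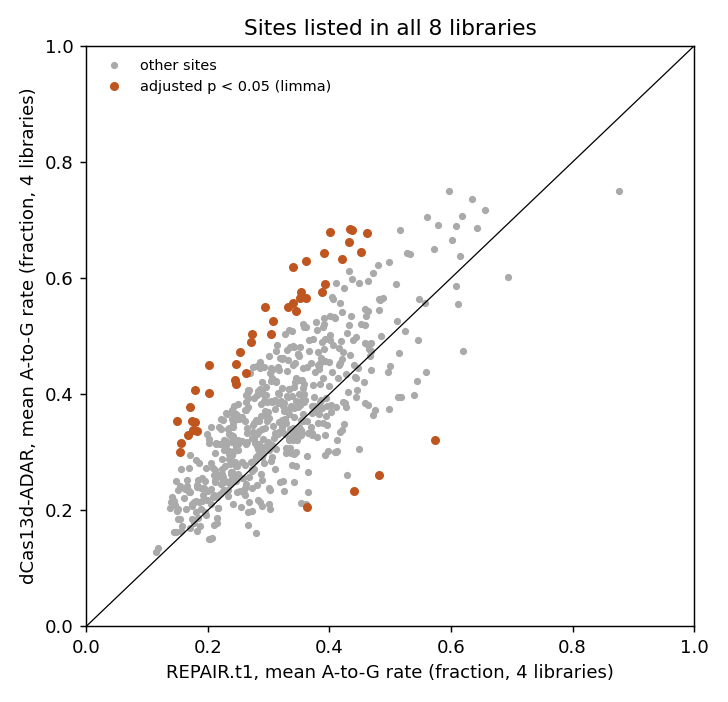
Mean A-to-G rate (fraction) in 4 dCas13d-ADAR libraries against the mean in 4 REPAIR.t1 libraries for the 609 sites listed in all 8, with the line of equal levels. Orange points are the 44 sites with an adjusted p below 0.05 in limma, 40 above the line and 4 below it.

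Some sites were listed by every library of 1 of these editors and by none of the other. There were 178 such sites for dCas13d-ADAR, at a median level of 0.258, and 79 for REPAIR.t1, at a median level of 0.256. With 1 library left out these numbers were 228 to 307 and 92 to 149, and at a level of at least 0.2 they were 91 and 42. Leaving out a library loosens the rule and can only raise the numbers, and a minimum level can only lower them. The highest levels among them were at position 121437104 on chromosome 10 for dCas13d-ADAR (0.612 ± 0.0909, SD, n = 4) and position 135614083 on chromosome 7 for REPAIR.t1 (0.429 ± 0.0821, SD, n = 4). Both positions were picked after their values were seen.

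Of the sites listed in every DECOR and dCas13d-ADAR library, most had lower levels in DECOR. Over these 25 sites, of 295 common to both editors, the mean level was 0.199 ± 0.0116 in DECOR (SD, n = 2) and 0.331 ± 0.0116 in dCas13d-ADAR (SD, n = 4), with 24 of the 25 lower in DECOR and an exact permutation p of 0.133, the smallest possible. Over the 97 to 126 sites in both lists of a pair of libraries, DECOR minus dCas13d-ADAR was smaller, at -0.0765 to -0.0568 (8 pairs). In limma 12 of the 25 passed an adjusted p of 0.05, all lower in DECOR; with sites missing from at most 1 library 17 of 91 passed, again all lower. The largest falls were at position 235277158 on chromosome 1, with 0.214 ± 0.00485 in DECOR (n = 2) against 0.687 ± 0.0703 in dCas13d-ADAR (n = 4; limma adjusted p = 2.6e-05), position 75113460 on chromosome 11, with 0.168 against 0.627 (limma adjusted p = 1.8e-05), and position 60668789 on chromosome 11, with 0.164 against 0.482. Positions 6500041 and 122931900 on chromosome 11, position 35101241 on chromosome 9, and positions 39711447 and 35804547 on chromosome 22 were lower in DECOR by 0.145 to 0.246, and position 146015798 on chromosome 8 and position 18799396 on chromosome 16 by 0.0912 to 0.132. The number passing was 7 without dCas13d-ADAR NT replicate 1 and 7 without DECOR MALAT1 replicate 1.

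The share of listed sites on most chromosomes differed between dCas13d-ADAR and REPAIR.t1 libraries. Chromosome 19 held 12.8% ± 0.333 of the dCas13d-ADAR sites and 8.37% ± 0.442 of the REPAIR.t1 sites (SD, n = 4 each), with 10.4% ± 0.203 in DECOR (n = 2). Chromosomes 16, 20 and 22 also held larger shares in dCas13d-ADAR, at 6.29% against 4.81%, 3.36% against 2.81% and 5.28% against 3.86%. Chromosome 1 held 11.4% ± 0.243 of the dCas13d-ADAR sites and 13.04% ± 0.324 of the REPAIR.t1 sites, and chromosome 2 held 4.45% against 5.87%. Of 23 chromosomes, 16 differed, 4 with a larger and 12 with a smaller share in dCas13d-ADAR (two-sided exact permutation p = 0.0286 each, adjusted p = 0.0411 over 23). Shares of 1 list sum to a whole, so the chromosomes are not independent tests, and this comparison was chosen after the lists were seen.

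**Figure D4:**
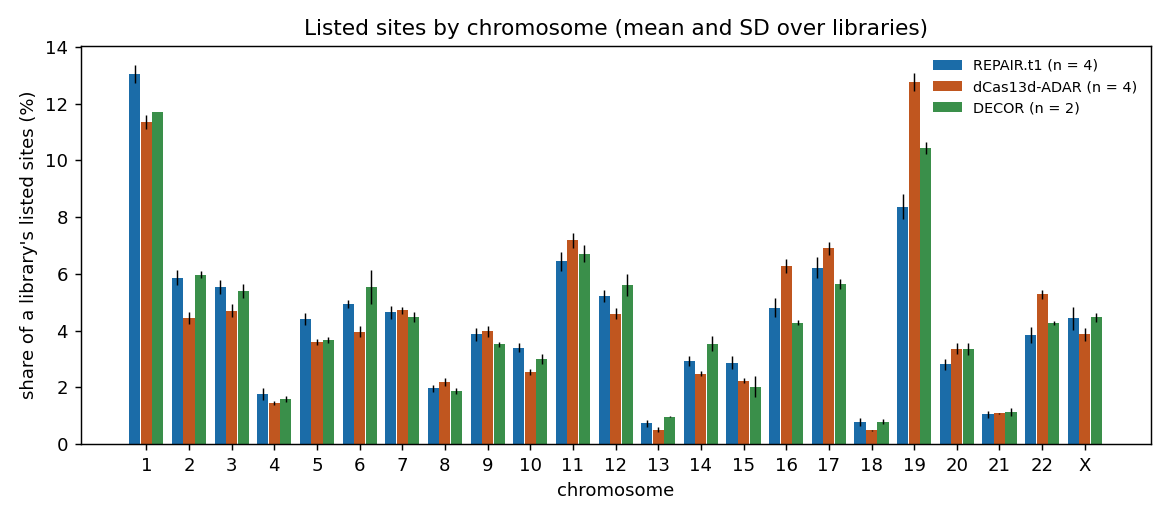
Share of a library's listed sites (percent) on each chromosome for REPAIR.t1 (n = 4), dCas13d-ADAR (n = 4) and DECOR (n = 2), as bars from 0 with the mean and SD over libraries. Chromosome 19 holds 12.8% of the dCas13d-ADAR sites, 10.4% of the DECOR sites and 8.37% of the REPAIR.t1 sites.

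Among distances of 1 to 12 bases, pairs of sites in the DECOR lists were most often 2 bases apart, a distance that was rarer in the other lists. Pairs of listed sites 2 bases apart numbered 28.3 ± 2.29 per 1000 sites in DECOR (SD, n = 2), 6.07 ± 0.937 in REPAIR.t1 (n = 4) and 4.02 ± 0.218 in dCas13d-ADAR (n = 4). Pairs of adjacent bases ran the other way, with 5.54 ± 0.109 per 1000 in DECOR, 15.0 ± 0.537 in REPAIR.t1 and 10.5 ± 0.763 in dCas13d-ADAR. At 3 bases the values were 15.3 ± 1.76, 8.88 ± 0.653 and 8.56 ± 1.25 in the same order. Another listed site lay within 50 bases of 32.7% ± 0.176 of DECOR sites (SD, n = 2), 25.4% ± 0.512 of dCas13d-ADAR sites and 21.5% ± 0.668 of REPAIR.t1 sites (SD, n = 4 each). Spacing was examined after the lists were seen and was not tested.

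**Figure D5:**
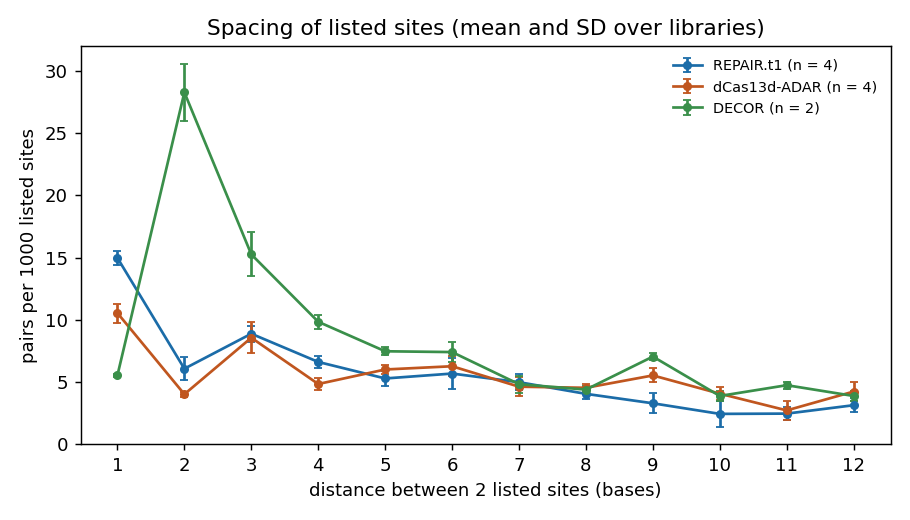
Pairs of listed sites at each distance from 1 to 12 bases, per 1000 listed sites, as the mean and SD over libraries of REPAIR.t1 (n = 4), dCas13d-ADAR (n = 4) and DECOR (n = 2). DECOR peaks at 2 bases with 28.3 pairs per 1000 sites, while REPAIR.t1 and dCas13d-ADAR have their highest values at 1 base, 15.0 and 10.5.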

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

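Apart from leaving out libraries, 130 alternatives were computed, and in 90 a result kept its direction and its side of the threshold or moved less than the spread; 6 lost a call, 0 gained a call, 32 moved a value by more than the spread and 2 turned a direction. The added alternatives named as such under the processing were chosen after seeing the data. Minimum levels of 0.1 and 0.2 ended no call on site numbers. Depth was not recorded, so its effect was not tested. Not run, for want of read counts, were the coverage minima and the tests on counts; not run, for want of an annotation or sequence of the build, were the alternatives without target gene sites, for gene lists and regions, and for sequence context.

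With sites in both libraries of a group, site ratios were 115.6 for REPAIR.t1 over REPAIRv2, 162.6 for dCas13d-ADAR over REPAIRv2, 1.41 for dCas13d-ADAR over REPAIR.t1, 0.712 for DECOR over dCas13d-ADAR and 1.00 for DECOR over REPAIR.t1, and median level differences were 0.0162 for dCas13d-ADAR minus REPAIR.t1, 0.0260 for dCas13d-ADAR minus REPAIRv2, -0.0759 for DECOR minus dCas13d-ADAR and -0.0597 for DECOR minus REPAIR.t1. That of REPAIR.t1 minus REPAIRv2 turned to 0.00981, and the DECOR over REPAIR.t1 site ratio turned to 0.932 at a level of at least 0.2. The guide ratio lost its call without the REPAIRv2 libraries (1.03). With NT libraries alone 2 sites and with EZH2 libraries alone 0 sites passed between dCas13d-ADAR and REPAIR.t1, on fewer libraries. The cause of the other changes was not tested.

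At a level of at least 0.2, sharing was 71.6% for REPAIRv2 with REPAIR.t1, 71.5% with dCas13d-ADAR, 42.1% for REPAIR.t1 replicates, 42.4% for its guides, 40.9% for REPAIR.t1 with dCas13d-ADAR, 48.1% for dCas13d-ADAR replicates, 47.8% for its guides, 29.6% for DECOR replicates, 0.822% for REPAIR.t1 with DECOR and 1.36% for dCas13d-ADAR with DECOR. Within 50 bases, the wider definition gave 17.8% for REPAIRv2 with DECOR, 51.1% for REPAIR.t1 replicates, 51.5% for its guides, 49.9% for REPAIR.t1 with dCas13d-ADAR, 57.5% for dCas13d-ADAR replicates, 57.4% for its guides, 48.1% for DECOR replicates, 14.3% for REPAIR.t1 with DECOR and 16.03% for dCas13d-ADAR with DECOR.

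Leaving out 1 library, no site ratio or mean level difference between editors could pass 0.05 with 3 against 4 libraries or fewer. Ratios ranged over 62.8 to 81.6 (REPAIR.t1 over REPAIRv2), 78.3 to 101.7 (dCas13d-ADAR over REPAIRv2), 1.22 to 1.26 (dCas13d-ADAR over REPAIR.t1), 0.953 to 1.01 (DECOR over dCas13d-ADAR), 1.19 to 1.26 (DECOR over REPAIR.t1), 76.9 to 99.9 (DECOR over REPAIRv2) and 1.26 to 1.33 (EZH2 over NT; exact permutation p 0.0185 to 0.0370). Median level differences ranged over -0.00519 to 0.00437 (REPAIR.t1 minus REPAIRv2) and -0.00277 to 0.00679 (EZH2 minus NT), both crossing 0. The mean level difference at shared sites ranged over 0.0440 to 0.0531. Sharing ranged over 23.9% to 33.3% (REPAIRv2 replicates), 28.3% to 40.2% (its guides), 6.43% to 7.94% (REPAIRv2 with DECOR), 44.9% to 45.7% (REPAIR.t1 replicates) and 49.7% to 51.1% (dCas13d-ADAR replicates). Sites passing in limma ranged over 10 to 44 for dCas13d-ADAR against REPAIR.t1 (10 without dCas13d-ADAR NT replicate 1), 0 to 1 for the difference of the guide effect and 7 to 11 for DECOR against dCas13d-ADAR. Where an arm kept 1 library, that library was assumed to vary like the others.

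Replicate numbers are shared across groups, but nothing in the labels ties them to a batch. Between the REPAIR.t1 and dCas13d-ADAR groups, log odds differences between replicates correlated at -0.015 to 0.055 over the 609 shared sites. REPAIRv2 and DECOR were not checked, and a batch acting on depth or site numbers would not show there. A shared batch is therefore not excluded. With the replicate block, site ratios of 70.7, 88.1 and 1.25 and the mean level difference of 0.0496 lost their call, at the smallest p that 4 pairs allow, and the guide ratio of 1.30 lost its call, at an exact permutation p of 0.0625; 44 sites passed between dCas13d-ADAR and REPAIR.t1 in limma, as without the block.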

Other observations

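Chosen after the results were seen were the read length comparison for DECOR, the level comparison at shared REPAIRv2 sites, with the rule that reads it, and the test of dense clusters as the whole cause of the chromosome shares; the other tests were set before their result was seen.

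Among REPAIR.t1 and dCas13d-ADAR sites, those listed by more libraries had higher levels. Of the 17194 sites listed by REPAIR.t1 or dCas13d-ADAR, 8372 (48.7%) were in 1 of the 8 libraries and 609 (3.54%) in all 8, and the median level was 0.250 for the first and 0.338 for the second. In the dCas13d-ADAR NT group, 41.3% of sites below a level of 0.2 were in the other library, against 71.4% of sites at 0.5 or above. For DECOR these shares were 35.8% and 52.6%, with 35.1% from 0.2 to 0.3. In REPAIRv2 EZH2_A22 they ran the other way, at 35.6% (16 of 45) and 12.5% (1 of 8), and in REPAIRv2 NT they were 6.90% (2 of 29) and 0% (0 of 4), with 34.4% (11 of 32) from 0.2 to 0.3 and 33.3% (9 of 27) from 0.3 to 0.5.

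The difference between dCas13d-ADAR and REPAIR.t1 was set against other ways of splitting their 8 libraries into 4 and 4. The editor split gave 44 sites past the threshold in limma, and 1 of the 35 splits, the editor split itself, gave as many; the highest other split gave 1. For sites listed by all libraries of 1 side and none of the other, the editor split gave 257, again the most in 1 of 35 splits, and the highest other gave 44. A share of 1 in 35 is the smallest this design allows, so chance in the grouping is made less likely but is not excluded. The other splits also leave the editor difference in the spread, which lowers their number of sites passing in limma.

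DECOR lists held few positions of the other editors. A coordinate shift between the lists is argued against, since at any shift of 1 to 10 bases either way at most 0.726% of the 2067 sites in both DECOR libraries met a REPAIR.t1 or dCas13d-ADAR site, against 4.50% at no shift. Coverage of wholly other stretches of the genome is argued against only at a scale of 2000 bases. Of those sites, 83.7% had a REPAIR.t1 or dCas13d-ADAR site within 2000 bases, against 2.61% and 2.47% after moving them by 1 Mb either way. Within 500 bases the share was 70.2% and within 50 bases 37.7%. All libraries hold polyadenylated RNA of 1 cell line, so nearby sites are likely whatever the editor. Whether coverage differs from base to base cannot be told from these shares. The sequencing run and read length cannot be told apart from the editor and the guide, because 0 DECOR libraries had the read lengths of the other editors. A hypothesis left open is that DECOR may edit other adenosines in the same regions; the frequent spacing of 2 bases bears on which adenosines, but needs the sequence, which was not used here.

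REPAIRv2 listed more sites with EZH2_A22 than with NT. Sites directed by the guide are argued against as the bulk of the gain, since 87.9% (109 of 124) of the sites in an EZH2_A22 list and no NT list of REPAIRv2 were in an NT list of another editor, against 76.1% (35 of 46) of the sites in an NT list alone. Deeper libraries cannot be told apart from more editing: at the 35 sites listed on both sides the median level was 0.0423 higher with EZH2_A22 (95% bootstrap interval over sites 0.00452 to 0.0595, 26 of 35 higher), but without NT replicate 1 it was 0.0253 (-0.0129 to 0.0667) and without EZH2_A22 replicate 2 it was 0.0373 (-0.00853 to 0.0832), and over all listed sites the difference in median level of EZH2_A22 minus NT was -0.00295. More editor protein in the EZH2_A22 cells was not tested and stays open too.

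Sites of dCas13d-ADAR lay more often on chromosomes 16, 17, 19 and 22 than those of REPAIR.t1, with 31.2% ± 0.818 against 23.3% ± 0.802 (SD, n = 4 each). These 4 were picked after the shares were seen, as chromosomes rich in G and C by general knowledge; chromosome 17 did not pass by itself (adjusted exact permutation p = 0.0692), and with chromosome 20, which passed, in its place the difference was 7.85 percentage points against 7.98. Sites of low level near the listing threshold are argued against, since 104.9% of the difference was left among sites at a level of at least 0.3. Dense clusters of sites are argued against as the whole cause, since 5.66 percentage points of the difference were left when sites within 2000 bases were counted as 1; that 71.0% of the difference was left keeps open whether clusters add to it. What the sites on these chromosomes share could be a property of their transcripts or of the amounts of those transcripts, which no test here addressed.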
